A study of Homo sapiens with 38 samples.

How the data were processed

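The samples were MCF-7 cells, a human breast cancer epithelial line that carries the oestrogen receptor, in 3 transgenic versions that each express a doxycycline-inducible protein. RNA was sequenced from 22 libraries in 8 groups, and chromatin immunoprecipitation (ChIP) with an antibody to the mCherry tag was sequenced from 8 libraries, each with an input library. Per the labels, RNA libraries were made from poly(A)-selected RNA with a strand-specific kit. Induction for RNA lasted 10, 24 or 48 h at a doxycycline dose of 1.0 µg/mL, and for ChIP 15 h at 0.1, 0.5 or 1.0 µg/mL. Groups and replicate numbers were taken from the sample titles.

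Per the submitters' processing notes, the tools used upstream were cutadapt 4.1, STAR 2.7.1, HTSeq 0.11.1, DESeq2 1.44.0, FastQC 0.11.9, Trimmomatic 0.39, Bowtie2 2.4.2 and MACS2 2.2.9.1, on builds GRCh38.p12 and hg38. The notes give no roles, order or settings for these tools. The authors deposited whole-number read counts per Ensembl feature in 1 table, with no normalization. The authors' deposited tables for the 5 induction comparisons hold log2 fold changes and p-values with adjusted p-values, which were used only beside the values computed here. The authors deposited a broad peak list per ChIP library, with a score, a fold enrichment and −log10 p and q values for each peak, so peaks were called per library and not on pooled replicates. Whether the input libraries served as the background of the peak calls is not given in the sources used here. The fold enrichments and −log10 q values in the text are the authors' own values per peak, and were compared within a list, except that regions shared by PCD-RFP replicates were ranked by the mean of their folds in both lists.

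The count table held 60662 Ensembl features, of which 60306 matched the reference table of gene names and 42039 had a symbol that was not an identifier. The 5 summary lines that name no gene were left out of library sizes and tests. Reads outside any feature made up 10.6 to 12.6% of the reads, ambiguous reads 3.47 to 3.66% and reads with several alignments 3.37 to 4.24%. Gene counts per library ran from 32.2 to 91.3 M, with a median of 73.4 M. The 10 most abundant genes took 5.75 to 6.91% of the gene counts.

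Differential expression was tested with edgeR 4.0.16 in R 4.3.3. All 22 libraries entered 1 quasi-likelihood fit with a mean for each of the 8 groups and 14 residual degrees of freedom. Library sizes were scaled with TMM, filterByExpr by group kept 20779 features, and p-values were adjusted with the Benjamini-Hochberg method over all of them, with a two-sided threshold of 0.05. Each induced group was compared with uninduced cells of the same line, and 4 further contrasts tested differences between responses at 24 h or between induction times. Levels are TMM-scaled CPM, counts relative to library size, as mean ± SD over libraries, and log2 fold changes carry their standard error (SE). Adjusted p-values of single genes come from this edgeR test unless another source is named.

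The genes named were set by a rule written before the data were examined. For an induction comparison it took up to 10 genes per direction with the largest fold change among those past the test, with an absolute log2 fold change of at least 1, a mean of at least 1 CPM in the higher group, every induced library on the same side of every uninduced library, and a symbol that is not clone-based. Where fewer than 5 passed on a side, the fold requirement was dropped there. For a difference or time comparison it took up to 5 per direction without the library condition. It also took up to 4 members with the smallest p from each gene list, CBX8, the 5 regions shared by both PCD-RFP ChIP replicates with the highest mean fold, and up to 5 regions called in more than 1 SRA ChIP library.

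The 25 gene lists were written from textbook knowledge before the data were examined. They cover HOX genes, developmental regulators and signalling genes typically marked by H3K27me3, subunits of both Polycomb complexes, interferon-stimulated genes, MHC genes, NF-kB and cytokine genes, oestrogen response genes, luminal markers, basal and mesenchymal markers, and markers of fibroblasts, endothelium and leukocytes. The others are cell cycle genes, cyclin-dependent kinase inhibitors with senescence genes, p53 targets, ATF4 targets, unfolded protein response genes, heat shock genes, mitochondrial-genome genes, glycolysis and hypoxia genes, cholesterol synthesis genes, immediate early genes, cancer-testis antigens, histone genes and neuronal genes. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation. Several lists share members (XBP1 and STC2, for example), so their results are not independent.

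Peak sets were compared by interval overlap in Python 3.11.15. A peak counted as shared when it overlapped by at least 1 bp. Each share stands beside the mean over 100 random placements of the same peak widths on the same chromosomes, and beside a local version, added after the peaks were seen, that placed each peak within its own 5 Mb window. Exact Clopper-Pearson 95% intervals are given for shares. These intervals cover counting error only. The planned set of genes near a peak used transcription start sites, which need strand, and the annotation used here (GRCh38.p14) gave none. Genes whose body overlaps a region called in both PCD-RFP ChIP replicates were used in their place, and this was decided after the peak lists were opened. Gene positions on the main chromosomes were matched by symbol, for 17690 tested genes.

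The edgeR step was tested on simulated data drawn from the real means and library sizes of 20779 genes, with 50 genes changed at each of 4 sizes. At an absolute log2 change of 0.25 it recovered 64% of changed genes for SRA at 10 h, 76% for SRA at 24 h, 76% for PCD-RFP and 58% for RFP-VP64. At 0.5 the shares were 86, 92, 94 and 92%, and at 1 they were 98, 100, 100 and 100%. False calls made up 4.40, 5.64, 7.96 and 4.37% of calls in the same order (8, 11, 16 and 8 calls, from a single draw each). The values for SRA at 24 h and PCD-RFP lay above the nominal 5%, though on few calls. Far fewer genes were changed than the real comparisons called, so the recovered and false shares may differ there. Changed genes were drawn from those with an expected count of at least 50, so the recovered shares do not cover genes of lower expression.

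Replicates of a group were compared before they were averaged. Chi-square per degree of freedom between replicates ran from 1.86 to 6.47, so no pair looked like 2 copies of a library. The labels do not say that RNA replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, only the compared groups in the fit, a replicate block, a 2-fold requirement, each library left out in turn, stricter peaks and other overlap definitions. Thinning all libraries to the shallowest, gene bodies extended by 5000 bp and peaks of a single PCD-RFP replicate were added after the data were seen. The 5 Mb windows and their number, 10, were also chosen after the peaks were seen. Input libraries had no peak lists and were not analysed here, and read coverage was not analysed here.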

Results

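MCF-7 cells carrying 1 of 3 doxycycline-inducible fusion proteins were profiled. PCD-RFP joins the chromodomain of CBX8, a Polycomb repressive complex 1 subunit that binds the repressive histone mark H3K27me3, to a red fluorescent protein. SRA (synthetic reader-actuator) adds VP64, a synthetic transcriptional activation domain, to PCD-RFP. RFP-VP64 lacks the chromodomain. RNA was sequenced from SRA cells before induction (3 libraries) and after 10 h (2), 24 h (3) and 48 h (3) of doxycycline, from PCD-RFP cells before (3) and after 24 h (3), and from RFP-VP64 cells before (3) and after 24 h (2). Gene counts ran from 32.2 to 91.3 M per library. ChIP for the mCherry tag was done in duplicate for PCD-RFP at 1.0 µg/mL and for SRA at 0.1, 0.5 and 1.0 µg/mL.

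The CBX8 transcript, part of which the PCD-RFP and SRA transgenes encode, was measured first as a check of the labels. It stood at 38.1 ± 0.27 CPM (SD, n = 3) in uninduced PCD-RFP cells and 678 ± 19.1 (n = 3) after induction. In SRA cells it rose from 33.7 ± 0.51 (n = 3) to 142 ± 4.35 at 10 h (n = 2), 141 ± 13.7 at 24 h (n = 3) and 153 ± 6.05 at 48 h (n = 3). In RFP-VP64 cells, whose transgene has no chromodomain, it was 32.7 ± 0.73 (n = 3) before and 35.4 ± 0.93 (n = 2) after. The log2 response of SRA minus that of PCD-RFP cells at 24 h was -2.09 ± 0.06 (SE), with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 5.51e-30. Counts per gene do not separate the transgene from the endogenous gene. The feature ENSG00000273189, which was picked after its values were seen, went from 1.35 ± 0.23 to 94.5 ± 2.66 CPM in PCD-RFP cells and from 0.262 ± 0.09 to 18.4 ± 1.63 in SRA cells at 24 h. In RFP-VP64 cells it went from 0.434 ± 0.18 to 1.56 ± 0.10.

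**Figure D1:**
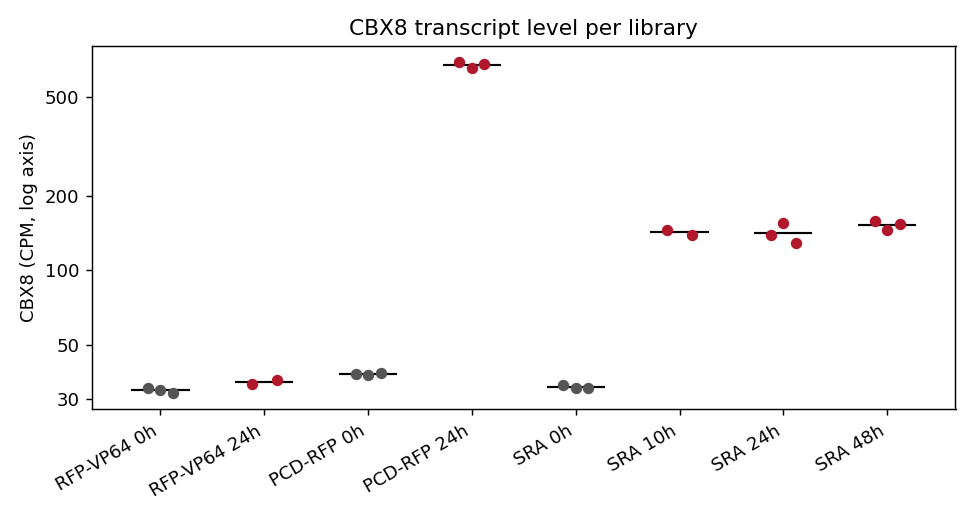
CBX8 transcript level in CPM on a log axis for each RNA library, with uninduced libraries in grey, induced libraries in red and a line at each group mean. Induced PCD-RFP libraries average 678 CPM, induced SRA libraries 141 to 153 CPM, and RFP-VP64 libraries 35.4 CPM.

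Each fusion was carried by 1 line, and the lines differed before induction. The first principal component of log2 CPM took 44.2% of the variance and placed every SRA library between 29.8 and 40.7 and every library of the other lines between -44.3 and -31.5. Every comparison below was therefore made within a line, or between the responses of lines. No cells without a transgene were treated with doxycycline among the libraries analysed here.

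The comparison of SRA cells at 10 h with uninduced cells asked which genes had changed by the first time sampled. The other lines were sampled uninduced and at 24 h alone. Changes at 10 and 48 h, and between times, therefore have no control line. Effects of the fusion there cannot be told apart from those of doxycycline, handling or time in culture. RHBDL3, a rhomboid-like membrane protein, rose from 0.277 ± 0.07 to 2.03 ± 0.18 CPM, a log2 change of 2.81 ± 0.23 (SE, n = 2 and 3, adjusted p = 3.11e-13). GALNT16, a glycosyltransferase that starts mucin-type O-glycans, rose by 1.92 ± 0.10 on the log2 scale, and NOVA2, a neuronal splicing factor, by 1.75 ± 0.16. CNTFR, a receptor for ciliary neurotrophic factor, rose by 1.97 ± 0.27, NRXN2, a synaptic adhesion protein, by 1.86 ± 0.27, and FLT1, a receptor for vascular endothelial growth factor, by 1.63 ± 0.24. TMCC2, FNDC5 (the precursor of irisin) and B4GALNT3 rose by 1.52 ± 0.17, 1.49 ± 0.19 and 1.48 ± 0.16. KRT6A, a keratin of stratified epithelia, fell by 1.51 ± 0.12, SOX21, a developmental transcription factor, by 1.40 ± 0.18, and TP63, a basal epithelial transcription factor, by 1.12 ± 0.13. CYP24A1, which degrades vitamin D, fell by 1.01 ± 0.12, and the non-coding RNAs LINC02154, LINC02015 and MIR3150BHG fell by 1.34 ± 0.28, 1.27 ± 0.13 and 1.03 ± 0.23.

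Of 32 measured HOX genes, which set position along the body axis and are classical Polycomb targets, 12 rose, 0 fell and 20 did not pass at 10 h (14 higher and 1 lower adjusted over the list alone). HOXC8 rose by 1.07 ± 0.25, HOXB9 by 0.83 ± 0.13, HOXC9 by 0.64 ± 0.12 and HOXC13 by 0.24 ± 0.06. The list was called higher by camera (adjusted p = 0.000508, and 0.00706 with an estimated correlation). Of 70 developmental regulators 13 rose and 8 fell (16 and 8 adjusted over the list alone), with MSX1 at 0.80 ± 0.12, LHX2 at 0.51 ± 0.07 and SOX9 at -0.32 ± 0.05, and the list was not called (adjusted p = 0.111). Of 43 signalling ligands and receptors 10 rose and 5 fell, the same counts as adjusted over the list alone, with NGFR at 1.33 ± 0.11 and GFRA1 at -0.36 ± 0.03 (adjusted p = 0.16, not called). Among 24 subunits of Polycomb repressive complex 1, with CBX8 left out, 6 rose and 2 fell, the same counts as adjusted over the list alone, led by BCORL1 at 1.03 ± 0.05 (list adjusted p = 0.00585, and adjusted p = 0.0682 with an estimated correlation).

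Genes of the oestrogen response fell in the same cells. Of 35 measured, 25 fell, 1 rose and 9 did not pass (28 lower and 1 higher adjusted over the list alone), among them MYC at -0.68 ± 0.04, AREG, an EGF receptor ligand, at -0.64 ± 0.04, XBP1 at -0.60 ± 0.03 and STC2 at -0.56 ± 0.03. Camera gave an adjusted p of 9.4e-36, and 0.00354 with an estimated correlation. Of 22 luminal markers 19 fell and 0 rose (19 and 1 adjusted over the list alone), with ESR1, the oestrogen receptor itself, at -0.50 ± 0.03, KRT19 at -0.36 ± 0.03 and KRT18 at -0.33 ± 0.03 (adjusted p = 6.22e-27, and 0.000385 with an estimated correlation). Of 29 immediate early genes 14 fell and 3 rose, with DUSP4 at -0.58 ± 0.03 and EGR3 at -0.55 ± 0.05 (adjusted p = 9.9e-12, and 0.00706 estimated). Of 13 histone genes, a list that includes the linker histone H1-0, 6 fell and 0 rose, with H2BC8 at -0.62 ± 0.06 and H2AC6 at -0.41 ± 0.04 (adjusted p = 3.91e-07, and 0.00706 estimated). Counts adjusted over these lists alone were the same. Polyadenylated histone transcripts are the part that poly(A) selection keeps.

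Further lists at 10 h lost their call with an estimated correlation. Of 34 glycolysis and hypoxia genes 20 fell and 2 rose (22 and 4 adjusted over the list alone), led by EGLN3 at -0.42 ± 0.04 and PFKFB3 at -0.33 ± 0.04 (adjusted p = 3.91e-07, and adjusted p = 0.332 with an estimated correlation). Of 21 basal and mesenchymal markers 6 fell and 2 rose, also adjusted over the list alone, with CD44 at -0.55 ± 0.04 and CAV1 at -0.75 ± 0.07 (adjusted p = 0.0125, and adjusted p = 0.118 with an estimated correlation). Of 47 interferon-stimulated genes 11 rose and 1 fell (13 and 1 adjusted over the list alone), with TAP1 at 0.36 ± 0.05 and OASL at 0.35 ± 0.07 (adjusted p = 0.0361, and adjusted p = 0.532 with an estimated correlation). Of 21 MHC genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with HLA-F at 0.44 ± 0.08 and HLA-B at 0.29 ± 0.06 (adjusted p = 0.0246, and adjusted p = 0.308 with an estimated correlation). Of 46 cell cycle genes 8 fell and 0 rose at this time, also adjusted over the list alone, and the list was not called (adjusted p = 0.111). In all, 3947 of 20779 genes passed the test at 10 h, 1932 higher and 2015 lower, of which 227 changed at least 2-fold (167 higher and 60 lower). The count was 2369 without replicate 2 of the 10 h group and 2548 without replicate 3, with the remaining library assumed to vary as the other groups did.

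After 24 h of SRA induction, SAMD14 rose by 2.13 ± 0.27 on the log2 scale (SE, n = 3 and 3), RHBDL3 by 2.04 ± 0.22, and CARNS1, which makes the dipeptide carnosine, by 1.82 ± 0.09. CARNS1 went from 2.11 ± 0.23 to 7.48 ± 0.32 CPM (SD, adjusted p = 3.04e-21). SLC17A7, a vesicular glutamate transporter, rose by 1.80 ± 0.13, SHANK1, a postsynaptic scaffold, by 1.77 ± 0.24, NRXN2 by 1.63 ± 0.24 and NOVA2 by 1.48 ± 0.15. GALNT16 rose by 1.56 ± 0.09 and ESRRG, an orphan nuclear receptor, by 1.45 ± 0.12. KRT6A fell by 2.00 ± 0.10, from 5.91 ± 0.14 to 1.48 ± 0.08 CPM, and KRT81, KRT13 and KRT4 fell by 1.12 ± 0.04, 1.12 ± 0.08 and 1.28 ± 0.17. H19, an imprinted non-coding RNA, fell by 1.34 ± 0.06, from 29.0 ± 3.04 to 11.3 ± 0.61 CPM (adjusted p = 4.06e-23). CXCL8, a neutrophil chemokine, fell by 1.25 ± 0.17, NEGR1 by 1.22 ± 0.14, SPRR1B, a cornified envelope protein, by 1.10 ± 0.10, SOX21 by 1.33 ± 0.15 and LINC02154 by 1.45 ± 0.23.

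The cell cycle list fell nearly as a whole at 24 h. Of 46 genes 45 fell, 0 rose and 1 did not pass, with the same counts adjusted over the list alone, among them MCM7 and MCM4 of the replicative helicase at -0.40 ± 0.03 and -0.37 ± 0.03, the licensing factor CDT1 at -0.45 ± 0.03 and TOP2A at -0.37 ± 0.03. Its adjusted p was 3.34e-45, and 0.0142 with an estimated correlation. Of the oestrogen response genes 31 fell and 1 rose, with the same counts adjusted over the list alone, led by STC2 at -0.63 ± 0.03, AREG at -0.63 ± 0.03 and XBP1 at -0.61 ± 0.03 (adjusted p = 3.32e-37, and 0.00557 estimated). Of the luminal markers 15 fell and 2 rose, with SPDEF at -0.54 ± 0.03 and ESR1 at -0.39 ± 0.03 (adjusted p = 9.64e-14, and 0.00604 estimated). Of 36 amino acid response and ATF4 target genes 17 fell and 2 rose, with DDIT4 at -0.64 ± 0.04 and GDF15 at -0.48 ± 0.04 (adjusted p = 3.05e-07, and 0.0317 estimated). Of the immediate early genes 16 fell and 3 rose, with DUSP4 at -0.52 ± 0.03, MYC at -0.54 ± 0.03 and JUN at -0.32 ± 0.03 (adjusted p = 5.64e-08, and 0.0317 estimated). Counts adjusted over these 3 lists alone were the same.

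Glycolysis and hypoxia genes were lower for 22 members and higher for 2 (23 and 3 adjusted over the list alone), with PGK1 at -0.32 ± 0.03 and HK2 at -0.37 ± 0.04 (adjusted p = 2.18e-09, and adjusted p = 0.252 with an estimated correlation). Of the basal and mesenchymal markers 10 fell and 3 rose (11 and 3 adjusted over the list alone), and the integrin subunit ITGA6 was among those that rose, at 0.50 ± 0.04 (adjusted p = 0.00848, and adjusted p = 0.111 with an estimated correlation). Of the MHC genes 9 rose and 2 fell (11 and 2 adjusted over the list alone), with HLA-B at 0.49 ± 0.05 and HLA-A at 0.34 ± 0.04 (adjusted p = 0.0148, and adjusted p = 0.252 with an estimated correlation). The HOX list was not called at 24 h (adjusted p = 0.409), with 6 members higher and 2 lower, also adjusted over the list alone. Of 17 neuronal genes 4 rose and 1 fell, also adjusted over the list alone, led by SLC17A7 and by L1CAM at 0.34 ± 0.04, and the list was not called (adjusted p = 0.257). Of 16 markers of fibroblasts, endothelium and leukocytes 4 rose, 1 fell and 11 did not pass (5 and 2 adjusted over the list alone), with COL1A1 at 0.61 ± 0.04, COL5A1 at 0.61 ± 0.05 and COL6A3 at -0.97 ± 0.10 (adjusted p = 0.257). The mean of that list was below 0 and its median above.

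Lists that were called in no induction comparison followed at 24 h of SRA. Of 13 Polycomb repressive complex 2 subunits 5 fell and 1 rose, also adjusted over the list alone, with EZH2, its methyltransferase, at -0.22 ± 0.03, JARID2 at -0.22 ± 0.03 and PHF1 at 0.36 ± 0.04 (adjusted p = 0.355). Of 18 NF-kB and cytokine genes 4 rose and 3 fell (6 and 3 adjusted over the list alone), with IER3 at -0.33 ± 0.03 and NFKBIE at 0.27 ± 0.06 (adjusted p = 0.913, with a test direction below 0 and a median above). Of the 13 genes of the mitochondrial genome 7 rose and 0 fell (9 and 1 adjusted over the list alone), with MT-ATP6 at 0.16 ± 0.04 (adjusted p = 0.17). Of 5 measured cancer-testis antigens 1 passed, SSX1 at 2.19 ± 0.84 (adjusted p = 0.554 for the list), a call lost when any of 5 single libraries was left out, and 0 passed adjusted over the list alone. Of the developmental regulators 10 rose and 9 fell (10 and 8 adjusted over the list alone), with HHEX at 0.57 ± 0.05 and DLX4 at 0.64 ± 0.10 (adjusted p = 0.821). Of the signalling genes 7 rose and 7 fell (8 and 7 adjusted over the list alone), with CHRD at 0.89 ± 0.10 and DKK1 at -0.32 ± 0.03 (adjusted p = 0.821). In all, 5809 genes passed at 24 h, 2964 higher and 2845 lower, and 240 of them changed at least 2-fold.

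At 48 h of SRA induction H19 had fallen by 2.21 ± 0.06 on the log2 scale, to 6.29 ± 0.79 CPM (SD, n = 3, adjusted p = 4.05e-30). SOX21 fell by 2.15 ± 0.16, its antisense RNA SOX21-AS1 by 1.38 ± 0.10, KRT6A by 2.14 ± 0.10, KRT4 by 1.61 ± 0.17 and KRT13 by 1.43 ± 0.08. CXCL8 fell by 1.56 ± 0.18, MSMB by 1.42 ± 0.12, CASP14, a caspase of keratinocyte differentiation, by 1.41 ± 0.17 and LINC02154 by 1.53 ± 0.23. The largest increases among the genes named were in RHBDL3 (1.99 ± 0.22), ESRRG (1.79 ± 0.12), GALNT16 (1.77 ± 0.08), CARNS1 (1.75 ± 0.09) and NOVA2 (1.70 ± 0.14), besides CBX8. COLEC12, a scavenger receptor, rose by 1.57 ± 0.20, DLG4, the postsynaptic scaffold PSD-95, by 1.46 ± 0.06 (from 5.10 ± 0.20 to 13.9 ± 0.97 CPM), SLC17A7 by 1.43 ± 0.13 and GNG13 by 1.30 ± 0.21.

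Of the cell cycle genes 44 fell and 0 rose at 48 h (45 and 1 adjusted over the list alone), with KIF20A at -0.50 ± 0.03 and CCNB1 at -0.41 ± 0.03 (adjusted p = 1.02e-40, and 0.0143 with an estimated correlation). Of the ATF4 targets 31 fell and 2 rose, with the same counts adjusted over the list alone, including DDIT4 at -0.87 ± 0.04 and PHGDH, which starts serine synthesis, at -0.40 ± 0.03 (adjusted p = 1e-22, and 0.00108 estimated). Of the oestrogen response genes 28 fell and 0 rose (29 and 0 adjusted over the list alone), with STC2 at -0.83 ± 0.03 and XBP1 at -0.76 ± 0.03 (adjusted p = 2.45e-42, and 0.0017 estimated). Of the luminal markers 15 fell and 3 rose, 16 and 3 adjusted over the list alone (adjusted p = 5.18e-14, and 0.00458 estimated). Of the immediate early genes 17 fell and 3 rose, 19 and 3 adjusted over the list alone (adjusted p = 3.42e-13, and 0.00619 estimated). Glycolysis and hypoxia genes were lower for 28 members and higher for 0, also adjusted over the list alone, with NDRG1 at -0.79 ± 0.06, EGLN3 at -0.61 ± 0.04 and BNIP3 at -0.50 ± 0.04 (adjusted p = 2.94e-19, and adjusted p = 0.0758 with an estimated correlation). Of 21 heat shock genes 11 fell and 1 rose, also adjusted over the list alone, with HSPB1 at -0.46 ± 0.03 and HSPE1 at -0.28 ± 0.03 (adjusted p = 0.00254, and adjusted p = 0.289 with an estimated correlation).

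Of 14 cyclin-dependent kinase inhibitors and senescence genes 8 fell and 2 rose at 48 h (9 and 3 adjusted over the list alone), and LMNB1, a lamin whose loss is a sign of senescence, was among those that fell, at -0.44 ± 0.03, with IGFBP3 at -0.68 ± 0.06 and CDKN1B at -0.25 ± 0.03. Camera gave that list an adjusted p = 0.00221, and adjusted p = 0.0771 with an estimated correlation. Of the MHC genes 9 rose and 2 fell (10 and 2 adjusted over the list alone), with HLA-B at 0.47 ± 0.05 and HLA-DRB1 at -0.32 ± 0.04 (adjusted p = 0.00527, and adjusted p = 0.208 with an estimated correlation). In all, 6688 genes passed at 48 h, 3227 higher and 3461 lower, and 235 of them changed at least 2-fold (120 higher and 115 lower).

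**Figure D2:**
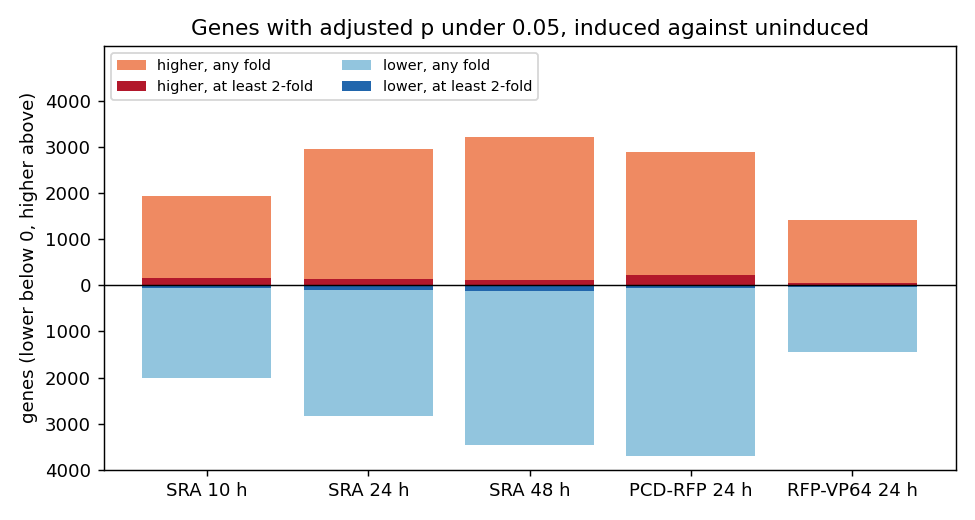
Number of genes past the edgeR test in each induction comparison, with genes higher after induction above 0 and lower genes below, and the genes changed at least 2-fold in the darker colour. Between 75 genes (RFP-VP64) and 283 genes (PCD-RFP) of 2876 to 6688 called changed at least 2-fold.

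PCD-RFP, the reader without an activator, was induced for 24 h in its own line. LGR5, a receptor for R-spondins known from stem cells, went from 0.0346 ± 0.007 to 1.40 ± 0.14 CPM (SD, n = 3 and 3, adjusted p = 5.33e-15), with a fold that is uncertain because of the level near 0 before induction. C1S, a complement protease, rose by 2.55 ± 0.19 on the log2 scale, FER1L6 by 2.48 ± 0.18, PLS3, an actin-bundling protein, by 2.38 ± 0.20, and DIO2, which activates thyroid hormone, by 2.35 ± 0.25. GALNT16 rose by 2.16 ± 0.08, METTL7A by 2.08 ± 0.12, CYP4F3 by 1.90 ± 0.19 and TUBB4A, a neuronal tubulin, by 1.87 ± 0.20. TGFB2, a transforming growth factor, fell by 1.30 ± 0.09, TP63 by 1.18 ± 0.18 (a call lost with thinning), EDN1, the vasoconstrictor endothelin, by 1.00 ± 0.08 and TGM2, a transglutaminase, by 0.96 ± 0.07. ADGRF1, SEMA3A, FOXI1 and LINC02015 fell by 0.87 ± 0.16, 0.81 ± 0.19, 0.80 ± 0.16 and 1.01 ± 0.10. RN7SL1 and RN7SL3, near-identical copies whose counts are uncertain, fell by 0.97 ± 0.16 and 0.89 ± 0.18.

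Targets of the p53 pathway rose with PCD-RFP. Of 28 genes 20 rose, 0 fell and 8 did not pass (22 and 0 adjusted over the list alone), with GDF15 at 0.59 ± 0.04, ZMAT3 at 0.32 ± 0.03, BTG2 at 0.29 ± 0.03 and TNFRSF10B, a death receptor, at 0.28 ± 0.03 (adjusted p = 1.67e-11, and 0.00706 with an estimated correlation). Of the interferon-stimulated genes 22 rose and 1 fell, with PARP14 at 0.86 ± 0.07, OAS1 at 0.54 ± 0.07 and IFIT5 at 0.44 ± 0.05 (adjusted p = 2.55e-05, and adjusted p = 0.299 with an estimated correlation). Of the MHC genes 10 rose and 0 fell, with TAP1 at 0.28 ± 0.05 (adjusted p = 0.00194, and adjusted p = 0.2 with an estimated correlation). Counts adjusted over these last 2 lists alone were the same. Of the cell cycle genes 45 fell and 0 rose, also adjusted over the list alone, with UHRF1 and E2F1 each at -0.49 ± 0.03 and MCM7 at -0.42 ± 0.03 (adjusted p = 2.67e-59, and 0.00706 estimated). Of the oestrogen response genes 29 fell and 1 rose (32 and 1 adjusted over the list alone), with MYC at -0.46 ± 0.03 and RET at -0.49 ± 0.04 (adjusted p = 8.77e-17, and 0.038 estimated). Of the histone genes 9 fell and 0 rose, also adjusted over the list alone, with H2BC21 at -0.35 ± 0.03 and the linker histone H1-0 at -0.29 ± 0.03 (adjusted p = 3.1e-05, and 0.038 estimated).

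Of the immediate early genes 15 fell and 3 rose with PCD-RFP (16 and 3 adjusted over the list alone), and FOSL1 was among those that rose, at 1.08 ± 0.08 (adjusted p = 0.00872, and adjusted p = 0.299 with an estimated correlation). Of the heat shock genes 11 fell (12 adjusted over the list alone) and 1 rose, HSPB8 at 0.77 ± 0.05 (adjusted p = 0.0376, and adjusted p = 0.404 with an estimated correlation). Of 23 cholesterol synthesis genes 9 fell and 2 rose, also adjusted over the list alone, with SQLE at -0.23 ± 0.03 and SREBF2 at -0.21 ± 0.03 (adjusted p = 0.0412, and adjusted p = 0.404 with an estimated correlation). The luminal list was not called (adjusted p = 0.114), with 14 members lower (15 adjusted over the list alone) and 3 higher, ELF5 at 0.77 ± 0.09 among them. Of the HOX genes 5 rose and 1 fell (4 and 1 adjusted over the list alone), with HOXA1 at 1.46 ± 0.15 and HOXD1 at 2.45 ± 0.66 (adjusted p = 0.293, not called). In all, 6601 genes passed, 2904 higher and 3697 lower. Of the 283 changed at least 2-fold, 237 were higher and 46 lower.

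RFP-VP64, the activator without a reader, was induced for 24 h as the control for VP64 and for doxycycline. BRSK1, a kinase of neuronal polarity, rose by 1.54 ± 0.17 on the log2 scale (SE, n = 2 and 3, adjusted p = 1.65e-09), CDH15, a muscle cadherin, by 1.40 ± 0.22, CARNS1 by 1.38 ± 0.12 and RND2, a Rho family GTPase, by 1.27 ± 0.17. PCP4L1, REEP2, PLEKHA4, NOVA2 and GNG7 rose by 1.25 ± 0.19, 1.15 ± 0.13, 1.13 ± 0.12, 1.11 ± 0.24 and 1.09 ± 0.16. APOE, a lipoprotein, was at 1.2 ± 0.25, a call that was lost without replicate 3 of the induced group. ADGRF1 fell by 1.38 ± 0.17, and the mucins MUC16 and MUC5AC fell by 1.16 ± 0.15 and 1.15 ± 0.08, the latter from 60.4 ± 5.46 to 27.3 ± 5.02 CPM. GALNT5, KRT4 and LINC02015 fell by 1.02 ± 0.14, 1.00 ± 0.17 and 1.10 ± 0.12.

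Of the oestrogen response genes 26 fell and 0 rose with RFP-VP64 (29 and 0 adjusted over the list alone), with CA12 at -0.53 ± 0.03, STC2 at -0.51 ± 0.03 and KRT13 at -0.95 ± 0.08 (adjusted p = 2.71e-39, and 0.00448 with an estimated correlation). Of the luminal markers 13 fell and 1 rose, with the same counts adjusted over the list alone, with XBP1 at -0.37 ± 0.03 and ESR1 at -0.31 ± 0.03 (adjusted p = 1.09e-11, and 0.0131 estimated). Of the cell cycle genes 30 fell and 0 rose (36 and 0 adjusted over the list alone), with MCM10 at -0.32 ± 0.04 and MCM5 at -0.25 ± 0.03 (adjusted p = 8.54e-22, and adjusted p = 0.117 with an estimated correlation). Of the ATF4 targets 10 fell and 1 rose, 13 and 1 adjusted over the list alone (adjusted p = 9.08e-05, and adjusted p = 0.117 with an estimated correlation). Of 23 unfolded protein response genes 7 fell and 0 rose (8 and 0 adjusted over the list alone), with CANX at -0.14 ± 0.03 (adjusted p = 0.00534, and adjusted p = 0.21 with an estimated correlation). Of the heat shock genes 8 fell and 0 rose (10 and 0 adjusted over the list alone), with HSPA8 at -0.19 ± 0.03 (adjusted p = 4.59e-05, and adjusted p = 0.21 with an estimated correlation).

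Of the cholesterol synthesis genes 7 fell and 2 rose with RFP-VP64 (9 and 3 adjusted over the list alone), with HMGCS1 at -0.18 ± 0.04 (adjusted p = 0.0432, and adjusted p = 0.609 with an estimated correlation). Of the immediate early genes 9 fell and 2 rose, also adjusted over the list alone, and EGR1 was among those that rose, at 0.68 ± 0.04 (adjusted p = 0.0164, and adjusted p = 0.384 with an estimated correlation). Of the MHC genes 8 rose and 0 fell (9 and 0 adjusted over the list alone), with HLA-A at 0.28 ± 0.04 (adjusted p = 0.00734, and adjusted p = 0.21 with an estimated correlation). In all, 2876 genes passed, 1427 higher and 1449 lower, and 75 changed at least 2-fold (45 higher and 30 lower). Without replicate 3 of the induced group the count was 1887, with the remaining library assumed to vary as the other groups did.

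Over the 5 induction comparisons, 45 of 125 list results were called, 10 higher and 35 lower, and 21 with an estimated correlation. In 41 of the 225 list results of all comparisons the median or the mean had another sign than the test, and 0 of these were called.

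**Figure D3:**
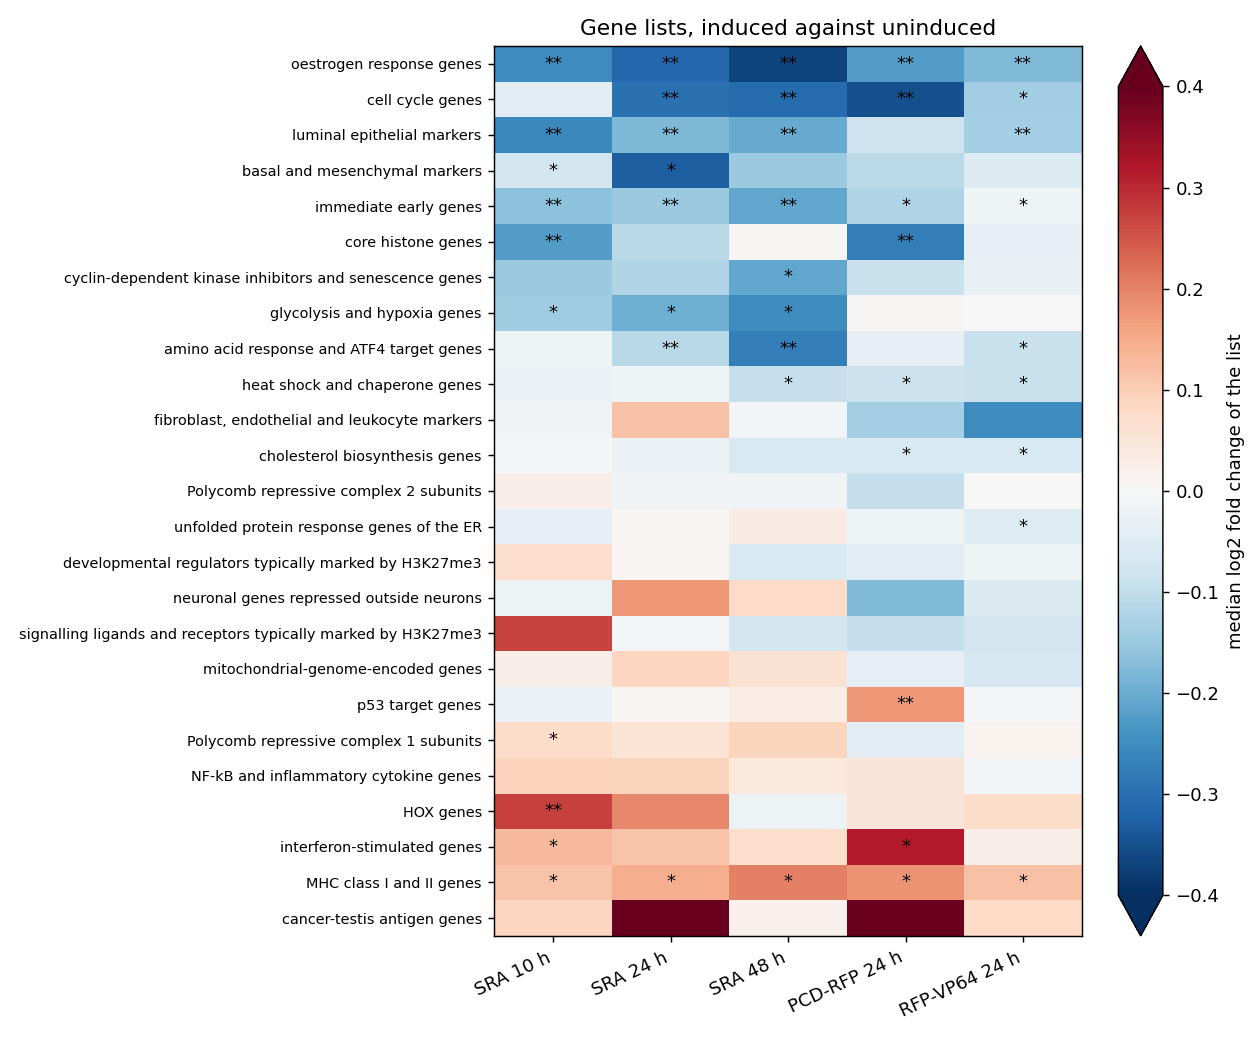
Median log2 fold change of each gene list in each induction comparison, from blue (lower after induction) to red (higher), with colours capped at 0.4 either way. A single asterisk marks a camera adjusted p under 0.05 at the preset correlation and a double asterisk marks lists that also pass with an estimated correlation, as the oestrogen response list does in all 5 comparisons.

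Calls were shared between lines, which have no control libraries in common. At 24 h, 1214 genes were higher in both SRA and PCD-RFP cells (414 for independent lists of these sizes) and 1557 lower in both (506). SRA and RFP-VP64 cells shared 1069 higher (204) and 1074 lower genes (198). PCD-RFP and RFP-VP64 cells shared 613 higher (199) and 887 lower genes (258). In all 3 lines 530 genes were higher (28.4) and 768 lower (35.3). Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.238, 0.25 and 0.123 for these pairs of lines, and Spearman's rho 0.265, 0.374 and 0.176. GALNT16, for example, rose by 1.56 ± 0.09 in SRA, 2.16 ± 0.08 in PCD-RFP and 0.47 ± 0.11 in RFP-VP64 cells, and LINC02015 fell by 0.96 ± 0.10, 1.01 ± 0.10 and 1.10 ± 0.12.

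The difference of the SRA and PCD-RFP responses at 24 h asked what the activation domain adds to the reader, in lines whose induced CBX8 levels also differed. RHBDL3 responded more in SRA cells, by 2.23 ± 0.32 on the log2 scale (adjusted p = 1.23e-06), as did ESRRG by 1.69 ± 0.19, SHANK1 by 1.64 ± 0.44, RBPMS2 by 1.55 ± 0.18 and COLEC12 by 1.52 ± 0.25. FER1L6 (-3.70 ± 0.38), DIO2 (-2.80 ± 0.39), METTL7A (-2.60 ± 0.17) and the imprinted gene PEG10 (-1.94 ± 0.14) responded in favour of PCD-RFP cells. PEG10 fell by 0.98 ± 0.10 in SRA cells and rose by 0.96 ± 0.09 in PCD-RFP cells. Of the p53 targets 17 were lower in the difference and 0 higher (20 and 0 adjusted over the list alone), with GDF15 at -1.06 ± 0.05 and MDM2 at -0.42 ± 0.04 (adjusted p = 1.74e-15, and 0.00274 with an estimated correlation). Of the luminal markers 12 were lower and 2 higher, also adjusted over the list alone, with CEACAM6 at -0.72 ± 0.05 and ELF5 at -1.30 ± 0.15 (adjusted p = 2.62e-08, and 0.0464 estimated). In all, 3544 genes differed, 2026 with a larger log2 change in SRA cells and 1518 with a smaller one, and 214 of them by at least 2-fold.

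The difference of the SRA and RFP-VP64 responses at 24 h asked what the chromodomain adds to the activator. RFP-VP64 carries no part of CBX8, so the induced level of this fusion was not measured and could differ between the lines. ESRRG responded more in SRA cells by 1.73 ± 0.24 (adjusted p = 4.39e-06), besides CBX8 by 1.95 ± 0.07, and DYNC1I1, a dynein chain, by 1.35 ± 0.31, a call lost with thinning. RHBDL3 was at 1.43 ± 0.37 and FMNL1-DT at 1.43 ± 0.41, both lost in the replicate block, with thinning and without single libraries of either line. KRT6A was lower in the difference by -1.48 ± 0.18, RAB7B by -0.97 ± 0.20, SOX21 by -0.91 ± 0.22, FBXO15 by -1.15 ± 0.27 and the pseudogene HLA-DRB6, whose reads can be shared with other HLA-DRB genes, by -0.95 ± 0.25. The calls of SOX21 (without replicate 2 of induced RFP-VP64), FBXO15 (without replicate 2 of uninduced RFP-VP64) and HLA-DRB6 (without any of 3 single libraries) were lost, as they were with thinning. RAB7B was at 0.01 ± 0.12 in SRA cells and rose by 0.98 ± 0.17 in RFP-VP64 cells. Of the cell cycle genes 15 were lower and 0 higher (32 and 0 adjusted over the list alone), with MCM7 at -0.22 ± 0.04 and CDT1 at -0.25 ± 0.05 (adjusted p = 5.87e-23, and adjusted p = 0.195 with an estimated correlation). Of the glycolysis and hypoxia genes 12 were lower and 1 higher (20 and 1 adjusted over the list alone), with BNIP3 at -0.41 ± 0.06 and CA12 at 0.46 ± 0.04 (adjusted p = 1.33e-12, and adjusted p = 0.247 with an estimated correlation). In all, 709 genes differed and 53.3% of them were higher in SRA cells, a share of 64.9% with RLE scaling, 65.5% with DESeq2 and 65.8% without replicate 2 of the uninduced RFP-VP64 group. The count was 340 without replicate 3 of the induced RFP-VP64 group.

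Between 10 and 24 h of SRA induction DUSP13 rose by 1.5 ± 0.16 on the log2 scale (n = 3 and 2, adjusted p = 2.81e-09), ATG9B by 0.96 ± 0.13 and ROM1 by 0.85 ± 0.09. LINC01484 and TOX3 were at 1.09 ± 0.27 and 0.82 ± 0.25, calls that were lost without replicate 2 of the 10 h group (TOX3 also without replicate 3 of it and without replicate 2 at 24 h). CSRP2, a LIM domain protein, fell by 0.92 ± 0.08, H19 by 0.91 ± 0.07, RGMA, a guidance molecule, by 1.03 ± 0.19, WFDC21P by 0.92 ± 0.18 and WNK3 by 0.94 ± 0.24, of which WNK3 was lost without replicate 3 of the 10 h group, and RGMA when all libraries were thinned to the shallowest. Of the cell cycle genes 43 fell and 0 rose (44 and 0 adjusted over the list alone), with UBE2C at -0.38 ± 0.04 and AURKB at -0.37 ± 0.04 (adjusted p = 1.59e-70, and 0.00592 with an estimated correlation). Of the HOX genes 5 fell and 0 rose, with the same counts adjusted over the list alone, with HOXB9 at -0.53 ± 0.12 and HOXC11 at -0.33 ± 0.08 (adjusted p = 0.00181, and 0.0168 estimated). Of the histone genes 7 rose and 2 fell, also adjusted over the list alone, with H2BC21 at 0.53 ± 0.03 and H2BC8 at 0.49 ± 0.06 (adjusted p = 2.98e-08, and 0.00822 estimated). In all, 2504 genes passed, 1344 higher and 1160 lower at 24 h, and 1233 passed without replicate 2 of the 10 h group and 1374 without replicate 3.

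Between 24 and 48 h H19 fell further, by 0.87 ± 0.07 (n = 3 and 3, adjusted p = 8.03e-12), and SLC47A1, a drug and cation exporter, by 0.67 ± 0.15. ADAM2 was at 0.69 ± 0.16, a call that was lost when all libraries were thinned to the shallowest. ABCA10, TCN1, TMPRSS11E and CACNB2 were at 0.71 ± 0.18, 0.70 ± 0.18, 0.65 ± 0.16 and 0.61 ± 0.18, and CDC42EP5, RBP7 and THEMIS2 at -0.65 ± 0.18, -0.59 ± 0.17 and -0.59 ± 0.17, all of them calls that were lost without 1 or more single libraries. Of the ATF4 targets 20 fell and 0 rose (25 and 1 adjusted over the list alone), with PHGDH at -0.27 ± 0.03 and SLC7A11, a cystine transporter, at -0.34 ± 0.04 (adjusted p = 6.01e-29, and 0.000277 with an estimated correlation). In all, 1086 genes passed, 468 higher and 618 lower at 48 h, and 446 passed without replicate 2 of the 24 h group, 637 without replicate 1 of the 48 h group and 468 without replicate 3 of it.

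The authors' deposited tables for the same 5 comparisons, made with DESeq2, called 3480 (SRA at 10 h), 5181 (24 h), 5926 (48 h), 5775 (PCD-RFP) and 2780 genes (RFP-VP64). Across genes, the log2 changes in the authors' deposited tables and those computed here had a Pearson's r of 0.995 to 0.998. Of the calls in the authors' deposited tables, 3428, 5121, 5887, 5705 and 2549 were also made here, all with the same sign.

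ChIP peak numbers differed widely between replicates. PCD-RFP ChIP had 4212 and 13477 broad peaks covering 2.65 and 10.5 Mb, with a median fold over background of 3.28 and 3.24 in the authors' lists. SRA ChIP had 14 and 302 peaks at 1.0 µg/mL, 6 and 20 at 0.5 µg/mL and 143 and 13 at 0.1 µg/mL, so numbers did not follow dose, and replicates of a dose differed as widely as doses did. Of each library's peaks, 5 or 6 lay on the mitochondrial genome, and in 1 SRA library at 0.5 µg/mL all 6 did. Of the peaks of PCD-RFP replicate 1, 40.8% (95% interval 39.3 to 42.3%) overlapped a peak of replicate 2, against 1.79% for random placement and 7.75% for placement within the same 5 Mb window. In the other direction the share was 11.3% (10.8 to 11.8%), against 0.551 and 2.30%. With a reciprocal overlap of 50%, 13.4% of replicate 1 peaks overlapped. Most PCD-RFP peaks were weak, and 125 and 187 had a −log10 q of at least 5.

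Of the SRA peaks, 93.4% (282 of 302, 95% interval 90 to 95.9%) and 100% (14 of 14, 76.8 to 100%) at 1.0 µg/mL overlapped a PCD-RFP peak. At 0.5 µg/mL the shares were 95% (19 of 20, 75.1 to 99.9%) and 100% (6 of 6, 54.1 to 100%), and at 0.1 µg/mL 97.9% (140 of 143, 94.0 to 99.6%) and 84.6% (11 of 13, 54.6 to 98.1%). With a reciprocal overlap of at least 50% the shares were 37.4, 50, 35, 83.3, 28.7 and 38.5% in the same order. For an overlap of at least 1 bp, placement within the same windows gave 17.9, 32.9, 27.2, 49.2, 20.5 and 37.2% in the same order. These values belong beside the first shares and not beside the reciprocal ones. For replicate 1 at 0.5 µg/mL, which had mitochondrial peaks alone, random placement reached 100% at its highest, so its share carries no weight. Mitochondrial peaks also made up 6 of 14 peaks of replicate 1 at 1.0, 6 of 20 of replicate 2 at 0.5 and 5 of 13 of replicate 2 at 0.1 µg/mL. Placement within the same windows reached 57.1, 55.0 and 69.2% at its highest in these libraries. Their shares thus rest in part on mitochondrial peaks.

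The regions shared by both PCD-RFP replicates with the highest mean fold lay on unplaced scaffolds (Un_KI270466v1, positions 343 to 1187 in replicate 1, folds of 10.5 and 5.29 in replicates 1 and 2, and Un_KI270467v1, 2045 to 3691, 7.80 and 5.27). Next to these they lay on chromosome 1 (106657350 to 106658517, 6.10 and 7.40, in no annotated gene), on chromosome 17 (62017138 to 62018312, 2.31 and 10.7, within MED13, a Mediator kinase module subunit) and on the mitochondrial genome (13719 to 14063, 5.48 and 6.03, within ND5). The place of the MED13 region rests on replicate 2, since its fold in replicate 1 lay below the median of that list, 3.28. All coordinates are on hg38. The regions called in the most SRA libraries were mitochondrial, at 9624 to 10418 (COX3 and ND3), 3120 to 3864 (ND1 and RNR2), 13727 to 14054 (ND5), 15272 to 16512 (CYTB) and 69 to 600, each in all 6 libraries. On the nuclear chromosomes, regions within BRIP1, a DNA repair helicase on chromosome 17 (61742930 to 61746351, for example), were called in 3 SRA libraries. The BRIP1 and MED13 regions lay in the peak-dense window of chromosome 17 from 60 to 65 Mb, where extra copies remain a candidate explanation. Whether the regions of this paragraph mark binding of the fusion was not tested.

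Peaks clustered along the chromosomes. Of the 1742 regions shared by the PCD-RFP replicates, 1733 lay on chromosomes 1 to 22, X and Y, and 68.2% of these fell in 10 of 631 windows of 5 Mb, 1.58% of the windows. Of all PCD-RFP peaks on these chromosomes, 38.4% (replicate 1, 1613 of 4203) and 24.2% (replicate 2, 3258 of 13457) fell there. The window of chromosome 17 from 60 to 65 Mb held 334 shared regions, that of chromosome 1 from 105 to 110 Mb held 159 and that of chromosome 8 from 85 to 90 Mb held 116. Of the SRA peaks on these chromosomes, 84.6% (replicate 2 at 1.0 µg/mL, 293 peaks) and 94.0% (replicate 1 at 0.1 µg/mL, 133 peaks) lay in the same 10 windows. The windows were ranked by the shared regions themselves, after these had been seen.

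**Figure D4:**
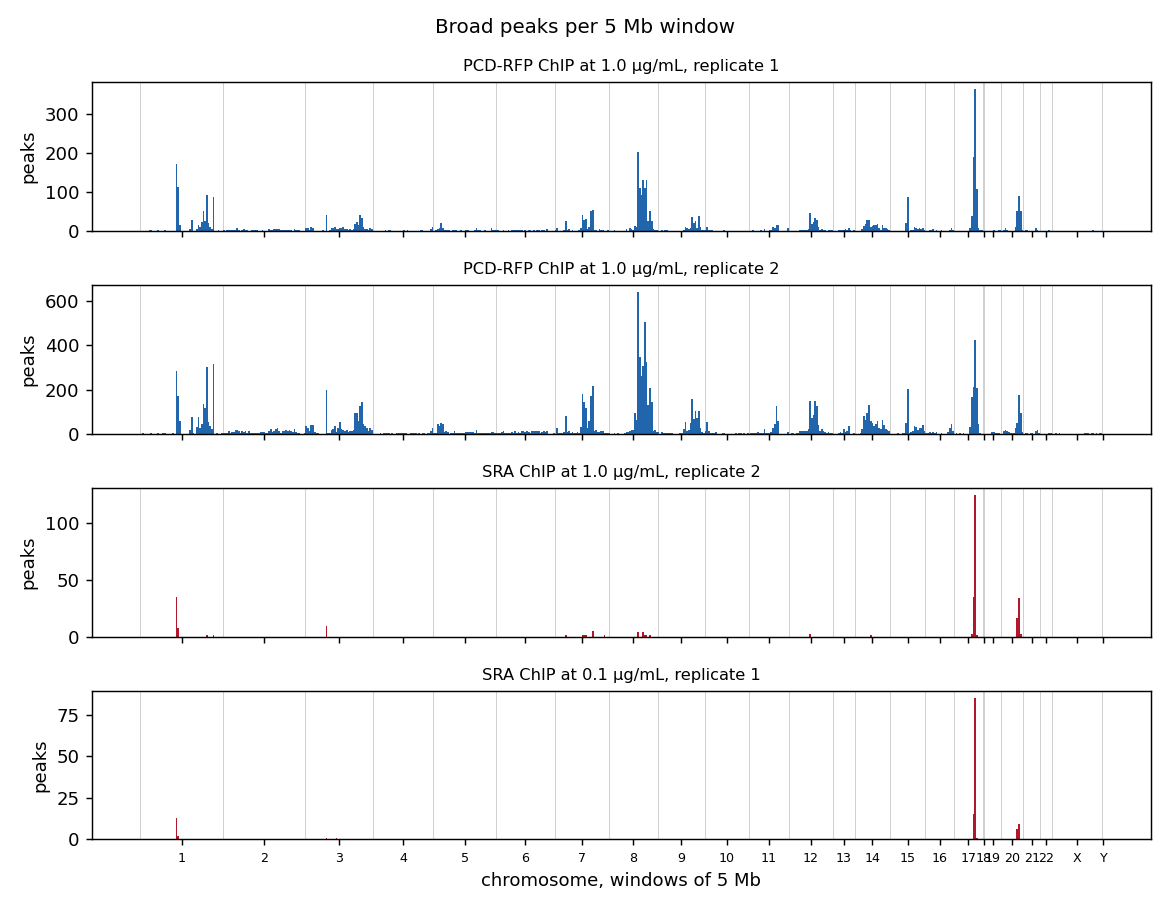
Number of broad peaks in each 5 Mb window along chromosomes 1 to 22, X and Y, for both PCD-RFP ChIP replicates (blue) and the 2 SRA ChIP libraries with the most peaks (red), each on its own scale. The window from 60 to 65 Mb of chromosome 17 holds 364 and 426 PCD-RFP peaks and 125 and 85 SRA peaks.

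The genes under shared PCD-RFP regions were compared with all others to relate occupancy to the RNA response. The bodies of 249 tested genes overlapped such a region, and their median length was 98.4 kb, against 24.2 kb for the other 17441. Camera called this set in none of the 5 comparisons, with median log2 changes of -0.0083 (SRA at 10 h, adjusted p = 0.365), -0.0068 (24 h, 0.61), 0.031 (48 h, 0.365), 0.0092 (PCD-RFP, 0.814) and 0.0049 (RFP-VP64, 0.814). With peaks of −log10 q of at least 5 the medians at 48 h of SRA and with RFP-VP64 turned to -0.020 each (adjusted p = 0.955), again not called. Counts of called genes, the other planned test, differed in 4 of 10 exact two-sided Fisher tests after adjustment. Of the overlapped genes 30.9% were higher at 48 h of SRA against 17.5% of the others (odds ratio 2.11, exact Fisher p = 3.67e-07, adjusted over the 10 tests 3.67e-06). Overlapped genes were also more often higher with PCD-RFP (22.9 against 15.4%, odds ratio 1.63, exact Fisher adjusted p = 0.00582). They were more often lower at 10 h of SRA (18.1 against 10.6%, odds ratio 1.86, adjusted p = 0.00198) and at 24 h (22.5 against 15.1%, odds ratio 1.64, adjusted p = 0.00582). With RFP-VP64, which has no chromodomain, 11.6 against 7.79% were higher (odds ratio 1.56, exact Fisher p = 0.0318, adjusted p = 0.0636). Gene sets matched on length and expression, a comparison extended to all 10 counts after these tests, changed this picture. The shares lower at 10 and 24 h of SRA were 22.5 and 21.3% in the median of the matched sets. Those of the overlapped genes, 18.1 and 22.5%, lay inside the central 95% of the matched sets (17.7 to 27.3% and 16.9 to 26.5%). The shares higher were 24.1% in matched sets at 48 h of SRA (central 95% 19.3 to 29.3%), 15.3% with PCD-RFP (10.8 to 19.7%) and 6.83% with RFP-VP64 (4.02 to 10.0%), each below that of the overlapped genes. With PCD-RFP and RFP-VP64 the shares lower, 22.1 and 9.64%, were below the matched ranges (22.5 to 32.5% and 10.4 to 18.5%).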

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

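The tests of thinned libraries, of peak fold inside the windows, of overlapped genes outside the windows, of matched sets in the other comparisons and of the shared oestrogen response and cell cycle lists, with the count of their member genes and its limit, were chosen only after the results were seen. The differences between the responses of 2 lines or between 2 induction times were marked because a test of the difference itself passed its threshold. The clustering of peaks, the genes overlapped by them and the lists lower in every line were not marked by such a test, and were taken up as patterns of interest.

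Responses at 24 h differed between SRA and PCD-RFP cells for 3544 genes, and 1 of 40 splits drawn from 200, the real one, gave as many. The highest other split gave 1135. Splits that mix induced with uninduced libraries add the induction response to the spread, which favours the real split. Chance is therefore not excluded for this count. Between SRA and RFP-VP64 cells 709 genes differed, a comparison with 2 libraries in a group, for which no splits were counted. In SRA cells 2504 genes differed between 10 and 24 h and 1086 between 24 and 48 h. For the 1086 genes the highest of the other splits called 0, and 1 of 10 splits, the real one, gave as many, which is too few splits for a share under 0.05. The same held for the 5809 genes changed at 24 h of SRA, the 6688 at 48 h and the 6601 with PCD-RFP, each with 0 in the highest of the other splits (1 of 10).

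Of the 25 lists, only those called with the preset correlation are given here. With a median of the SRA minus the PCD-RFP response above 0 these were Polycomb repressive complex 1 subunits (0.10, adjusted p = 0.141 with an estimated correlation), histone genes (0.20, adjusted p = 0.0657 with an estimated correlation), neuronal genes (0.17, 0.0578), mitochondrial-genome genes (0.090, 0.537) and cell cycle genes (0.055, 0.679). Cell cycle genes fell in both lines, with medians of -0.30 in SRA and -0.35 in PCD-RFP cells. Lower in the difference were p53 targets (-0.18, adjusted p = 0.00274 with an estimated correlation), luminal markers (-0.12, 0.0464), interferon-stimulated genes (-0.21, 0.471), glycolysis and hypoxia genes (-0.17, 0.208), immediate early genes (-0.084, 0.471), oestrogen response genes (-0.073, 0.415) and ATF4 targets (-0.062, 0.0773).

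Against RFP-VP64, the SRA response was lower in the median for glycolysis and hypoxia genes (-0.18, adjusted p = 0.247 with an estimated correlation), cell cycle genes (-0.14, 0.195), immediate early genes (-0.11, 0.195), oestrogen response genes (-0.051, 0.321), ATF4 targets (-0.049, 0.321) and luminal markers (-0.037, 0.247). It was higher for mitochondrial-genome genes (0.083, 0.321). From 10 to 24 h of SRA, HOX genes (-0.26, adjusted p = 0.0168 with an estimated correlation), signalling genes (-0.24, 0.0441), cell cycle genes (-0.24, 0.00592) and ATF4 targets (-0.086, 0.0441) were lower. Histone genes (0.22, 0.00822), luminal markers (0.090, 0.229) and mitochondrial-genome genes (0.053, 0.654) were higher. From 24 to 48 h, ATF4 targets (-0.15, adjusted p = 0.000277 with an estimated correlation), NF-kB and cytokine genes (-0.10, 0.131), and glycolysis and hypoxia genes (-0.093, 0.212) were lower. So were cyclin-dependent kinase inhibitors and senescence genes (-0.085, 0.18), developmental regulators (-0.079, 0.215), immediate early genes (-0.072, 0.131), oestrogen response genes (-0.052, 0.329) and heat shock genes (-0.030, 0.38).

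Genes in this paragraph were ranked among those past the test with a mean of at least 1 CPM in the highest of the groups compared and a symbol that is not clone-based, and genes of lower expression with larger differences were left out. The largest differences so ranked between the SRA and PCD-RFP responses were RHBDL3 (2.23), ESRRG (1.69), SHANK1 (1.64), RBPMS2 (1.55), and COLEC12 (1.52) on the side of SRA. On the other side they were FER1L6 (-3.70), DIO2 (-2.80), METTL7A (-2.60), CBX8 (-2.09) and PEG10 (-1.94). Between SRA and RFP-VP64 they were CBX8 (1.95), ESRRG (1.73), FMNL1-DT (1.43), RHBDL3 (1.43), DYNC1I1 (1.35) on the side of SRA. Lower were KRT6A (-1.48), FBXO15 (-1.15), RAB7B (-0.97), HLA-DRB6 (-0.95) and SOX21 (-0.91). From 10 to 24 h of SRA they were DUSP13 (1.5), LINC01484 (1.09), ATG9B (0.96), ROM1 (0.85), and TOX3 (0.82), which were higher at 24 h. Lower were RGMA (-1.03), WNK3 (-0.94), WFDC21P (-0.92), CSRP2 (-0.92) and H19 (-0.91). From 24 to 48 h they were ABCA10 (0.71), TCN1 (0.70), ADAM2 (0.69), TMPRSS11E (0.65), and CACNB2 (0.61), with lower values for H19 (-0.87), SLC47A1 (-0.67), CDC42EP5 (-0.65), RBP7 (-0.59) and THEMIS2 (-0.59).

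Of the regions on chromosomes 1 to 22, X and Y shared by the PCD-RFP replicates 68.2% lay in 10 windows of 5 Mb, against 38.4 and 24.2% of all peaks of the replicates, on chromosomes 1, 8, 17 and 20, chosen by shared peak count after the peaks were seen. Uninduced expression of the 320 genes there (median log2 CPM 4.79, against 3.74 for random sets of windows) lay at percentile 100 of the random sets, which is what extra copies would give, and stretches of chromosomes 1, 17 and 20 are known to be amplified in MCF-7. A high share of active chromatin would give the same value, so extra copies remain a candidate explanation. The median fold of shared peaks inside minus outside the windows was -0.17, and all peaks of replicate 1 gave 3.00 inside and 3.31 outside. Replicate 2 gave 3.25 inside and 3.24 outside, and folds exist only for called peaks, so a stronger enrichment there stays open. No biological explanation was tested, and input coverage, which would measure copy number, was not analysed here.

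Genes overlapped by shared PCD-RFP peaks were more often higher at 48 h of SRA, the largest of 10 Fisher tests, a choice for which the percentile below is not adjusted. Their share, 30.9%, lay at percentile 99.3 of gene sets matched on length and expression (median 24.1%, with 29.3% at the top of their central 95%), so length and expression, as matched here, account for part of the excess over 17.5%. Within the 10 windows the odds ratio was 1.33 (22.5% of 80 overlapped against 17.9% of 240 other genes, 95% interval 0.671 to 2.56, exact Fisher p = 0.411), which decides nothing, although it met the bound written beforehand for an effect of position. Outside the windows, a test chosen after that one, it was 2.52 (34.9% of 169 against 17.5%, exact Fisher p = 7.15e-08). Position in these 10 windows cannot account for genes outside them, but the cut at 10 was set after the peaks were seen. Windows just past it also held many shared regions, such as 53 on chromosome 8 from 90 to 95 Mb and 45 from 95 to 100 Mb. An effect of position in such windows therefore stays open, and genes that lie close together are not independent. The test outside the 10 windows was also not matched on length and expression, which may account for part of that excess. A biological explanation, occupancy by the fusion, is not established: camera called the set in 0 of 5 comparisons, RFP-VP64 without a chromodomain had an odds ratio of 1.56 and a share at percentile 99.6 of matched sets, and PCD-RFP and SRA are different lines.

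Oestrogen response and cell cycle genes were lower in every line at 24 h. For the oestrogen response list the highest camera adjusted p of the lines was 0.038 with an estimated correlation. An effect of doxycycline or handling would give this. In RFP-VP64 cells the list had a median of -0.18 and 26 of its 35 members fell. These values argue against a need for the chromodomain in the fall of those 26 members. The SRA minus the RFP-VP64 response of this list had a median of -0.051, so a part of its fall that needs the chromodomain stays open. For cell cycle genes, 30 of 46 members fell and 0 rose in RFP-VP64 cells (median -0.14). The limit for this count was set afterwards, and the members are not independent. The count argues only against a need for the chromodomain in the fall of those 30 members. The SRA minus the RFP-VP64 response had a median of -0.14, so a part of the fall that needs the chromodomain stays open. The median in RFP-VP64 cells alone decides nothing. An effect of doxycycline or handling stays open, because the highest adjusted p of the lines for that list was 0.117 with an estimated correlation. Effects of expressing any fusion stay open for both, as no cells without a transgene were treated with doxycycline among the libraries analysed here.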

How the results depend on the processing

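Thinning to the shallowest library, gene bodies extended by 5000 bp and overlap with a single PCD-RFP replicate were chosen only after the data were seen. No called result turned its direction under the alternatives that were run. With a 2-fold requirement, which by construction takes fewer genes, the counts were 227 (SRA at 10 h), 240 (24 h), 235 (48 h), 283 (PCD-RFP), 75 (RFP-VP64), 214 (SRA minus PCD-RFP), 36 (SRA minus RFP-VP64), 48 (24 against 10 h) and 16 (48 against 24 h). With an estimated correlation 21 of the 45 list calls were made. With the replicate block the counts were 3907, 5959, 6825, 6688, 2439, 3615, 658, 2592 and 1221 in the same order, and 46 lists were called.

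With a −log10 q of at least 5, which keeps fewer peaks by construction, 125 and 187 PCD-RFP peaks stayed, 6 and 21 of SRA at 1.0 µg/mL, 7 of replicate 2 at 0.5 and 15 of replicate 1 at 0.1 µg/mL. A separate setting kept peaks of any q on chromosomes 1 to 22, X and Y alone. It left 8 SRA peaks for replicate 1 at 1.0, 0 for replicate 1 at 0.5 and 4 for replicate 2 at 0.1 µg/mL. The share of replicate 1 PCD-RFP peaks that overlap replicate 2 was 76.8% at the stricter q, 13.4% with a reciprocal overlap of 50% and 49.8% within 1000 bp. The share of SRA peaks that overlap PCD-RFP peaks was 50 and 37.4% (1.0 µg/mL), 35% (replicate 2 at 0.5) and 28.7 and 38.5% (0.1 µg/mL) with a reciprocal overlap of 50%. It was 100% for replicate 2 at 0.5 µg/mL at the stricter q and within 1000 bp, and 86.7% for replicate 1 at 0.1 µg/mL at the stricter q. For genes under shared PCD-RFP regions, camera made no call at the stricter q (medians -0.0054, -0.0033, -0.020, 0.0089 and -0.020 for SRA at 10, 24 and 48 h, PCD-RFP and RFP-VP64) or with gene bodies extended by 5000 bp (-0.0083, -0.0055, 0.031, 0.0073 and 0.0061). Apart from what the settings do by construction, the cause was not tested.

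With each library left out in turn the counts ran from 2369 to 3529 (SRA at 10 h), 4958 to 5230 (24 h), 5561 to 6181 (48 h), 5326 to 5982 (PCD-RFP), 1887 to 2466 (RFP-VP64), 2803 to 3358 (SRA minus PCD-RFP), 340 to 726 (SRA minus RFP-VP64), 1233 to 2302 (24 against 10 h) and 446 to 1052 (48 against 24 h), and 42 to 47 lists were called. The lowest were without replicate 2 at 10 h (2369 and 1233), without replicate 3 of induced RFP-VP64 (1887 and 340) and without replicate 2 at 24 h (446). A lone library left in a group was assumed to vary as the other groups did. The share of SRA peaks of replicate 2 at 1.0 µg/mL that overlap a single PCD-RFP replicate was 81.5 to 90.7%.

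Of 842 results of named genes, 837 kept direction and side of the threshold with RLE scaling, 814 without a low-count filter, 828 with the replicate block, 831 with only the compared groups in the fit and 771 with thinned libraries, where 67 calls were lost. With DESeq2 788 did and 27 calls were lost, and the rest had no value. Of 125 list results 123 did with RLE scaling, 116 without a filter (8 were gained and 1 lost), 122 with the replicate block and 121 with only the compared groups in the fit. Counted over every fit with a library left out, 5137 gene results were kept and 507 calls were lost. In these fits 677 list results were kept, 14 calls were lost and 9 gained. Windows around transcription start sites of 5000 and 1000 bp were not run, since the annotation gave no strand. Depth limits calls of this kind: the 67 were lost at 32.2 M gene counts per library.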

Other observations

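The genes in this part were chosen as examples after their values were seen. ESRRG, an orphan nuclear receptor, rose with time in SRA cells, from 0.882 ± 0.04 CPM (SD, n = 3) to 1.87 ± 0.02 at 10 h (n = 2), 2.4 ± 0.07 at 24 h and 3.02 ± 0.12 at 48 h (n = 3 each). Its log2 change was -0.23 ± 0.15 (SE, adjusted p = 0.245) with PCD-RFP and -0.28 ± 0.20 (adjusted p = 0.439) with RFP-VP64. CARNS1, which makes carnosine, rose in all lines, by 1.82 ± 0.09 in SRA (24 h), 0.43 ± 0.11 in PCD-RFP and 1.38 ± 0.12 in RFP-VP64 cells. NOVA2, a neuronal splicing factor, rose by 1.48 ± 0.15, 1.25 ± 0.20 and 1.11 ± 0.24 in the same order. KRT6A, a keratin of stratified epithelia, fell by 2.00 ± 0.10, 0.45 ± 0.12 and 0.52 ± 0.15. CSRP2, a LIM domain protein, rose by 0.59 ± 0.08 at 10 h of SRA and fell by 0.33 ± 0.08 at 24 h and 0.44 ± 0.08 at 48 h. METTL7A rose by 2.08 ± 0.12 with PCD-RFP and fell by 0.53 ± 0.13 with SRA at 24 h.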
